A study of Homo sapiens with 6 samples.

How the data were processed

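RNA was measured by sequencing in 6 libraries of HCCLM3 cells, a human hepatocellular carcinoma line with high metastatic potential. The cells had received a lentivirus carrying either a control short hairpin RNA (shcontrol, 3 libraries) or a hairpin against ATXN7L3 (shATXN7L3, 3 libraries). Groups were taken from the treatment label and replicate numbers from the sample titles. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

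The deposited values are raw read counts per gene, 1 table for the series. Per the labels' protocols, RNA was extracted with Trizol and poly-A-tailed mRNA was selected. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, featureCounts of Subread 1.5.1, edgeR 3.12.1 and the build GRCh38. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited counts cover 34234 gene symbols. Near-identical counts for genes built on common exons (9024 for UGT1A3 and 8962 for UGT1A5 in shcontrol replicate 1) show that a read in a common exon was counted for each gene. Of the tested genes, 3124 (17.4%) overlapped exon bases of another gene on the same strand and 9598 (53.5%) on either strand. Reads of such genes, of antisense partners and of near-identical copies cannot be told apart in the counts.

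Gene types and GC content came from GENCODE 29 on the same build, which held 23443 of the symbols. Coordinates, strands and exonic lengths came with the deposited counts. A type was assigned to 23568 genes, and 121 symbols lay on more than 1 chromosome.

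Library totals ran from 22376867 to 23915783 counts. Genes were kept with the edgeR function filterByExpr (minimum count 10, minimum total 15), which left 17935. TMM factors lay between 0.972 and 1.02. The common biological coefficient of variation was 4.37%. Pairs of libraries were compared by chi-square over genes with at least 20 counts in the pair, where sampling noise alone gives 1 per gene. Pairs within shcontrol gave 3.62 to 6.56, pairs within shATXN7L3 1.59 to 2.19, so no library was treated as a repeat of another.

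Groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, group as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Levels are TMM-scaled counts per 1e6 counts (CPM), given as mean ± SD over 3 libraries. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F, which is an approximation. The target was also tested by a two-sided exact permutation test of log2 CPM (prior count 2).

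Before the data were examined, 36 gene lists were fixed from textbook knowledge, together with the tests, the alternatives and the rule for named genes. A list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists tested. Beside it stand camera with the correlation estimated per list, and fry, which tests whether the members of a list move one way on balance and does not compare them with other genes. The list of replication-dependent histone genes includes H1F0, which is a replication-independent linker histone, and was kept as fixed.

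The named genes are ATXN7L3, SMAD7, USP22 and ENY2, the 10 highest and 10 lowest log2 fold changes, and the 5 smallest p-values in each direction. From each list come up to 4 members past the threshold with the smallest p, or 2 with the highest CPM where none passed. The 10 highest and lowest were taken among protein-coding genes past the threshold with separated groups and an average log2 CPM of at least 2. Genes without an annotated type were not considered there. Some genes that the rule names are not reported here.

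The procedure was tested on a single set of simulated counts with the means and depths of these libraries. In it, 67, 67 and 66 genes were changed 1.25-fold, 1.5-fold and 2-fold. That is a much smaller share than the 24.2% of tested genes called in the real comparison. The rates below therefore need not carry over to it. Over 17725 simulated genes, edgeR recovered 55.2% of genes changed 1.25-fold, 71.6% of those changed 1.5-fold and 84.8% of those changed 2-fold. Of its 154 calls, 13 (8.44%) were false, above the 5% aimed at. DESeq2 recovered 47.8%, 61.2% and 74.2%, with 1.61% of its calls false. Camera called 0 of 50 random lists. The simulated genes varied independently, so this does not tell how camera treats lists whose members move together. The estimated correlation of the ribosomal proteins, for example, was 0.832.

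The alternatives were DESeq2 size factors, upper-quartile scaling, library size alone, no filter on low counts, a filter at a CPM of 1 in 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out in turn, and glmTreat against a fold of 1.5. A fit without the genes that overlap exon bases of another gene on the same strand was added after seeing the data. GC content and exonic length were examined with smooth terms of mgcv 1.9.3 and, for each of 3 lists, with the 20 nearest protein-coding genes outside the list per member. Tables were handled with pandas 2.3.3 in Python 3.11.15 and figures were drawn with matplotlib 3.10.9.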

Results

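Gene expression was measured by poly-A RNA sequencing in HCCLM3 hepatocellular carcinoma cells that had received a control hairpin or a hairpin against ATXN7L3, with 3 libraries in each group. The shcontrol libraries held 23033763, 22376867 and 22671480 counts and the shATXN7L3 libraries 22757031, 23915783 and 23608943. Mitochondrially encoded transcripts took 21.7% to 23.0% of the counts per library and the 10 most abundant genes took 18.4% to 19.5%. The first principal component (52.6% of the variance) separated the groups and the second (14.7%) spread the control libraries.

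ATXN7L3 encodes an adaptor of the deubiquitinase module of SAGA, a coactivator complex from which the module removes ubiquitin from histone H2B. Its mRNA fell from 37.1 ± 0.647 CPM in shcontrol to 20.2 ± 0.655 CPM in shATXN7L3 (mean ± SD, n = 3 each; edgeR adjusted p = 6.69e-10). The log2 fold change was -0.88 ± 0.056 (SE), which left 54.5% of the control level (50.4% to 58.9% at ± 2 SE). All shATXN7L3 libraries lay below all shcontrol libraries, and the exact permutation test gave p = 0.1, the smallest value 3 against 3 libraries allow. The gene lies on chromosome 17 from 44191805 to 44200113 on the minus strand (GRCh38).

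**Figure D1:**
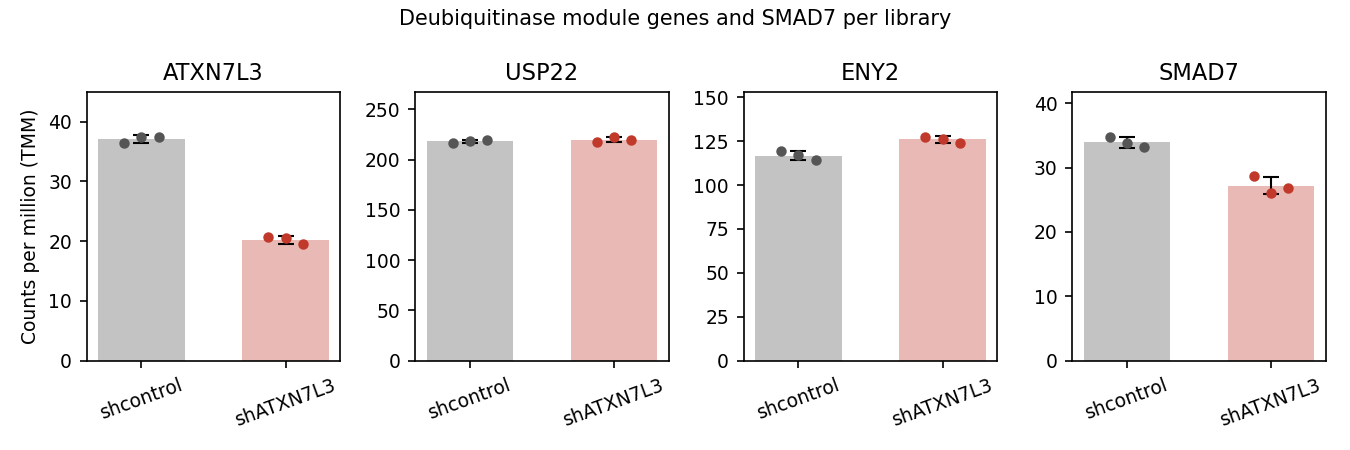
TMM-scaled CPM of ATXN7L3, USP22, ENY2 and SMAD7 in shcontrol and shATXN7L3 cells; dots are the 3 libraries of a group, bars their mean and error bars the SD, and each panel has its own axis from 0. ATXN7L3 was 37.1 against 20.2 CPM and SMAD7 33.9 against 27.2 CPM, while the means of USP22 were 218 and 220 CPM.

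Within the complex, the other parts of the module did not pass the test. USP22, its catalytic subunit, stood at 218 ± 1.44 CPM in shcontrol and 220 ± 2.77 CPM in shATXN7L3 (log2 fold change 0.01 ± 0.041, edgeR adjusted p = 0.864). ENY2, a small subunit of the module, had a log2 fold change of 0.11 ± 0.043 (edgeR adjusted p = 0.0724), which passed without shcontrol replicate 1 (0.0367) and with scaling by library size alone (0.0111). Of the 9 tested genes of the deubiquitinase module list, 1 fell, ATXN7L3 itself, and 0 rose, also when adjusted over the list alone (median 0.02, mean -0.10; camera adjusted p = 0.45, direction down). Of 18 other SAGA subunits, 2 rose and 0 fell, and 0 passed when adjusted over the list alone (median 0.03, mean -0.00; camera adjusted p = 0.872). The 2 that rose were TADA3 (0.18) and KAT2A (0.16), whose calls ended with DESeq2 (adjusted p = 0.0613 and 0.0922). TADA3 also lost its call without shcontrol replicate 2 (0.109) or 3 (0.0584) or shATXN7L3 replicate 1 (0.0704) or 2 (0.123), and KAT2A without shcontrol replicate 2 (0.0931) or shATXN7L3 replicate 1 (0.0585) or 3 (0.169). Of 16 genes of H2B ubiquitination and the PAF1 complex, 5 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.173); USP7, a ubiquitin protease, fell by 0.34 on the log2 scale (edgeR adjusted p = 7.71e-06). The calls of the PAF1 complex members were less firm: RTF1 (-0.13) and PAF1 (-0.14) lost theirs with DESeq2 (adjusted p = 0.0719 and 0.0586) and with scaling by library size alone (0.174 and 0.136). RTF1 also lost it with no filter (0.0826) and without shcontrol replicate 2 (0.12) or shATXN7L3 replicate 1 (0.1), 2 (0.096) or 3 (0.17). PAF1 lost it without shcontrol replicate 1 (0.0763) or 2 (0.11) or shATXN7L3 replicate 1 (0.285) or 3 (0.129), and LEO1 (-0.17) without shATXN7L3 replicate 1 (0.0523) or 2 (0.0591).

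Across the transcriptome, 2182 genes were higher and 2150 lower in shATXN7L3 among 17935 tested (edgeR, Benjamini-Hochberg adjusted p under 0.05). Of the 12955 protein-coding genes tested, 1878 were higher and 1855 lower. Called genes were 24.2% of all tested and a larger share of the protein-coding ones, such as the named list members. A list with about these shares of calls therefore shows no more than the background. Most differences were small: 78.1% of the called genes differed by less than 1.5-fold, 146 were at least 2-fold higher and 233 at least 2-fold lower. The groups were separated in 6861 tested genes (38.3%, where chance gives 10%). With scaling by library size alone, the split became 2955 higher and 1604 lower. DESeq2 called 1344 genes higher and 1510 lower, and the stricter filter left 92 genes at least 2-fold higher and 143 at least 2-fold lower. Some genes named here by the rule overlap exon bases of another gene on the same strand, and their values are uncertain to that extent. They are TF, CEACAM5, TMC5, TGFB2, AXIN2, MMP2, CLDN7, NOP58, KAT2A and CD68. Further named genes overlap exon bases on the opposite strand only, among them HMGA2, IGFBP5, FAM198B, SHISA9, THBS1, CTGF, CLDN2, CEBPA, FAS and NPC1. The strand setting of the counts is not given, so these values may be uncertain too.

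TF, the iron carrier transferrin (chromosome 3, 133745956 to 133779006), fell from 206 ± 20.2 to 35.9 ± 0.913 CPM (log2 fold change -2.52 ± 0.063, edgeR adjusted p = 3.96e-16). It overlaps exon bases of the pseudogene TFP1, which went from 16.5 to 3.71 CPM, so reads of the overlap cannot be told apart. PRKCB, protein kinase C beta (chromosome 16, 23836001 to 24220611), fell from 189 ± 7.52 to 49.6 ± 0.837 CPM (-1.93 ± 0.048, edgeR adjusted p = 3.96e-16). The collagen-binding proteoglycan LUM (-2.29 ± 0.090), the matricellular protein SPARCL1 (-1.69 ± 0.066), the IGF-binding protein IGFBP5 (-1.95 ± 0.11), FAM198B (-2.20 ± 0.096), SHISA9 (-1.83 ± 0.14) and SERPINA1 (-1.80 ± 0.10) fell as well. The carcinoembryonic antigen CEACAM5 fell from 152 ± 12.7 to 49.2 ± 2.38 CPM. The secreted mucin MUC5AC, among the 5 smallest p-values of this direction, fell from 310 ± 30.3 to 101 ± 6.04 CPM. CYP1A1, a xenobiotic-metabolising cytochrome, had a log2 fold change of -2.95 ± 0.49, but its control libraries spread over 5.87, 2.16 and 14.1 CPM, and without shcontrol replicate 3 the log2 fold change was -2.08.

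LAMA3, a laminin chain of epithelial basement membranes (chromosome 18, 23689443 to 23955066), rose from 88.7 ± 5.27 to 293 ± 10.8 CPM (log2 fold change 1.72 ± 0.050, edgeR adjusted p = 5.40e-15). IL13RA2, a decoy receptor for interleukin 13, rose from 127 ± 4.13 to 319 ± 0.470 CPM (1.33 ± 0.043, edgeR adjusted p = 3.42e-14). The architectural chromatin protein HMGA2 rose from 13.8 ± 0.498 to 37.7 ± 0.188 CPM and the adhesion molecule CLMP from 17.2 ± 1.33 to 49.9 ± 0.237 CPM. TMEM154 rose by 2.11 ± 0.15 on the log2 scale, from 1.53 ± 0.328 CPM. ANKRD29 (1.95 ± 0.097), KIAA1462, a junctional protein (1.79 ± 0.083), UNC13A (1.65 ± 0.10), TMC5 (1.43 ± 0.12), the Wnt ligand WNT7B (1.42 ± 0.10) and TRIM72 (1.33 ± 0.13) also rose.

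**Figure D2:**
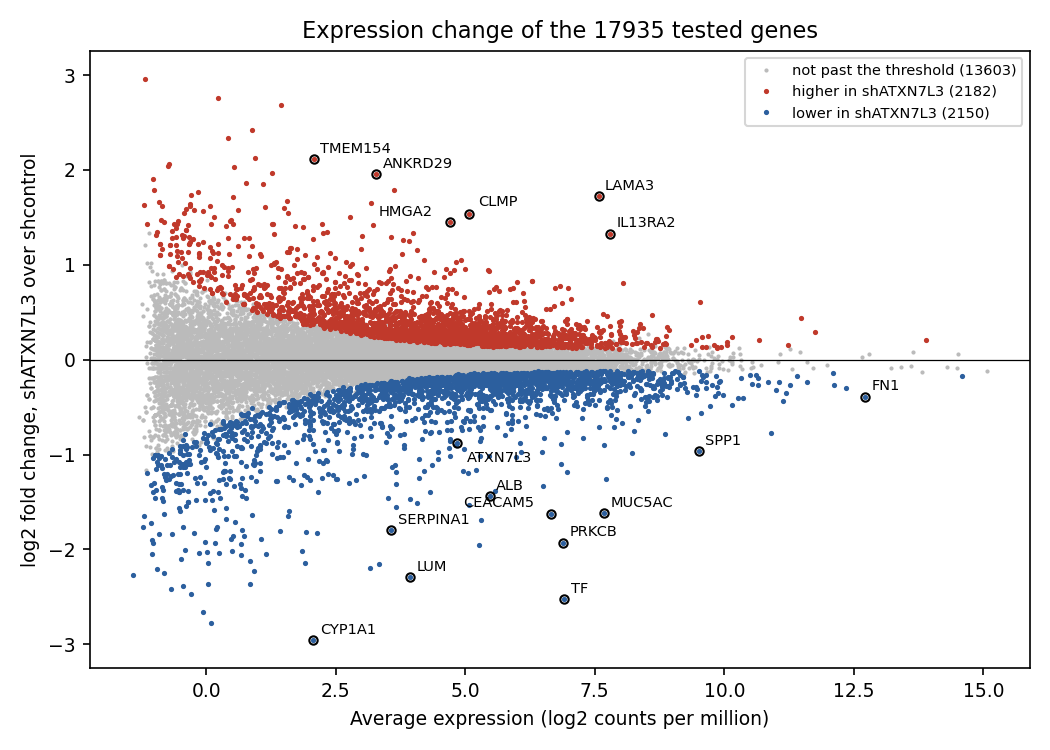
Log2 fold change of shATXN7L3 over shcontrol against average expression in log2 CPM for 17935 tested genes; red points are the 2182 higher genes, blue points the 2150 lower genes, grey points did not pass the threshold, and circles mark labelled genes. TF, PRKCB and MUC5AC lie among the lower genes of high expression, with log2 fold changes of -2.52, -1.93 and -1.62, and LAMA3 and IL13RA2 among the higher ones, with 1.72 and 1.33.

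Plasma proteins made by hepatocytes fell as a group. Of 20 tested, 15 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.83; camera adjusted p = 4.06e-37). This was the 1 list of 34 that kept its call with an estimated correlation (adjusted p = 0.0429 with an estimated correlation). ALB, albumin, fell from 65.2 ± 1.69 to 24.1 ± 1.15 CPM, SERPINA1, alpha-1-antitrypsin, from 18.6 ± 1.88 to 5.33 ± 0.675 CPM, and ITIH2, a hyaluronan-binding inhibitor chain, from 384 ± 11.7 to 228 ± 5.84 CPM.

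Liver transcription factors and metabolic enzymes were lower in 9 of 21 tested genes and higher in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 0.00153, adjusted p = 0.144 with an estimated correlation). They included the hepatocyte regulators HNF4A (-0.38 ± 0.054) and CEBPA (-0.44 ± 0.069), the xenobiotic receptor NR1I2 (-0.61 ± 0.12) and the gluconeogenic enzyme FBP1 (-1.28 ± 0.20). Cholangiocyte and progenitor markers went both ways, with 5 of 9 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 2.49e-04, adjusted p = 0.214 with an estimated correlation). The secreted phosphoprotein SPP1 fell from 966 ± 40.7 to 496 ± 4.93 CPM, CD24 and ONECUT2 fell by 0.52 and 0.65 on the log2 scale, and the keratin KRT19 rose by 0.40.

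In the TGF-beta and SMAD pathway, 13 of 26 genes fell and 3 rose, with the same counts adjusted over the list alone (median -0.12; camera adjusted p = 6.35e-05, adjusted p = 0.0633 with an estimated correlation). The inhibitory SMAD gene SMAD7 (chromosome 18, 48919853 to 48950711) fell from 33.9 ± 0.835 to 27.2 ± 1.33 CPM (log2 fold change -0.32 ± 0.057, edgeR adjusted p = 3.19e-04). THBS1, an activator of latent TGF-beta, fell from 267 ± 1.51 to 143 ± 3.01 CPM and the ligand TGFB2 from 87.1 ± 4.50 to 61.3 ± 2.13 CPM. The matricellular gene CTGF fell by 1.05 on the log2 scale. The 3 that rose were PMEPA1, by 1.43 from 0.716 CPM, ID3 (0.47) and SMURF2 (0.21). CTGF and TGFB2 are also members of the YAP list, and BMP4 belongs to this list and to the Wnt list.

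Of 16 Wnt pathway targets, 9 fell and 0 rose (10 and 1 adjusted over the list alone; median -0.26; camera adjusted p = 1.82e-06, adjusted p = 0.0564 with an estimated correlation). The feedback inhibitors NKD1 (-1.39 ± 0.075) and AXIN2 (-0.40 ± 0.049), the R-spondin receptor LGR5 (-1.94 ± 0.22) and the ligand BMP4 (-0.72 ± 0.092) were among them. YAP and TEAD targets were lower in 7 of 20 genes and higher in 3 (11 and 4 adjusted over the list alone; camera adjusted p = 0.0309, adjusted p = 0.525 with an estimated correlation). The coagulation initiator F3 fell by 0.61 and the receptor kinase AXL rose by 0.98 on the log2 scale. The call of this list ended without shcontrol replicate 1 (adjusted p = 0.0581), without shATXN7L3 replicate 2 (0.0744), with the stricter filter (0.0574), with DESeq2 (0.056) and without genes that overlap others on the same strand (0.378).

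Genes of invasion and metastasis moved in both directions, 10 of 21 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.173). Besides LAMA3, the integrins ITGB4 (94.3 ± 7.92 to 159 ± 1.86 CPM) and ITGA2 (35.8 ± 2.06 to 60.9 ± 3.31 CPM) rose. SPP1, also a member of this list, fell (-0.96 ± 0.043). Of 21 mesenchymal genes, 6 fell and 5 rose (9 and 6 adjusted over the list alone; camera adjusted p = 0.162, and 0.0419 without shcontrol replicate 3). The matrix genes COL6A3 (-1.39 ± 0.055), FN1 (-0.39 ± 0.046) and MMP2 (-1.06 ± 0.14) fell and the transcription factor ZEB2 rose (0.75 ± 0.094). Of 22 epithelial junction genes, 8 fell and 6 rose (8 and 9 adjusted over the list alone; median 0.01, mean 0.02, camera direction down, adjusted p = 0.418). The claudins split, with CLDN1 (-1.16 ± 0.057) and CLDN2 (-1.53 ± 0.092) lower and CLDN4 (0.34 ± 0.054) and CLDN7 (1.67 ± 0.17) higher.

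Markers of other cell types were few. Of 6 endothelial markers tested, PECAM1 fell (-0.64 ± 0.060) and ESAM rose (0.69 ± 0.076), as when adjusted over the list alone (camera adjusted p = 0.772). Of 4 tested leukocyte markers, LYZ fell, from 0.922 to 0.169 CPM, and CD68 rose, from 100 to 122 CPM. LUM was the 1 of 4 tested stellate cell and fibroblast markers that passed. Adjusted over the list alone, those counts were the same, and neither list had enough members for camera.

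Replication-dependent histone genes fell in 7 of 14 cases and rose in 1, H1F0 (8 and 1 adjusted over the list alone; median -0.65; camera adjusted p = 1.82e-06, adjusted p = 0.0564 with an estimated correlation). The linker histone HIST1H1C fell from 10.4 ± 0.308 to 4.32 ± 0.513 CPM, and HIST1H2AC (-0.73 ± 0.084), HIST1H2BK (-0.71 ± 0.083) and HIST2H4A (-0.93 ± 0.081) fell too. HIST2H4A has a near-identical copy and its value is uncertain. DNA replication genes were lower in 3 of 34 cases and higher in 0, also adjusted over the list alone (camera adjusted p = 0.68). These were POLE, RPA2 and MCM2, and each lost its call when shATXN7L3 replicate 2 (POLE, edgeR adjusted p = 0.0732) or 1 (RPA2, 0.076; MCM2, 0.0956) was left out, as did RPA2 without shcontrol replicate 2 (0.0501) and MCM2 without shATXN7L3 replicate 3 (0.0629) and with scaling by library size alone (0.0514).

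Of 35 mitosis genes, 6 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.229), among them the ubiquitin-conjugating enzyme UBE2C (0.30 ± 0.050). The calls of CENPE (0.40) and AURKA (0.15) ended with DESeq2 (adjusted p = 0.246 and 0.0551), that of AURKA also without shcontrol replicate 2 (0.108) or shATXN7L3 replicate 1 (0.0696) or 2 (0.169), and that of TOP2A (0.17) without shATXN7L3 replicate 3 (0.0549). Of 20 G1 regulators, 4 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.241). Cyclin CCND3 fell by 0.65, the kinase CDK6 by 0.36 and the inhibitor CDKN2B by 0.34 on the log2 scale. Of 25 p53 targets, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.144), with GADD45A at 0.46 ± 0.067 and the death receptor FAS at 1.64 ± 0.30 from 0.342 CPM. Of 24 apoptosis regulators, 6 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.297), with BIRC3 and CASP6 higher by 0.70 and 0.36 and BMF at -0.39.

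Cholesterol biosynthesis genes fell in 13 of 25 cases and rose in 1 (14 and 1 adjusted over the list alone; median -0.14; camera adjusted p = 8.65e-05, adjusted p = 0.435 with an estimated correlation). MSMO1, a sterol oxidase of the pathway, fell from 49.2 ± 2.99 to 32.4 ± 0.393 CPM and the squalene epoxidase SQLE from 260 ± 12.3 to 202 ± 3.45 CPM. Fatty acid genes went both ways, 10 of 27 higher and 8 lower (11 and 8 adjusted over the list alone; camera adjusted p = 0.481), with the elongase ELOVL6 at 0.70 ± 0.062 and the acyl-CoA synthetase ACSL3 at -0.44 ± 0.041.

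Hypoxia response genes were higher in 11 of 23 cases and lower in 4 (13 and 4 adjusted over the list alone; median 0.17; camera adjusted p = 0.00188, adjusted p = 0.477 with an estimated correlation). NDRG1 rose from 52.5 ± 2.60 to 85.3 ± 4.41 CPM, the angiogenic factor VEGFA from 68.1 ± 1.5 to 86.1 ± 2.86 CPM and the mTOR inhibitor DDIT4 from 15.3 ± 1.62 to 20.7 ± 1.06 CPM. Glycolysis genes were higher in 9 of 19 cases and lower in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.563 with an estimated correlation), and the call ended without shATXN7L3 replicate 2 (adjusted p = 0.0578). The enolase ENO2 rose from 18.5 ± 1.2 to 37.6 ± 1.56 CPM and the glucose transporter SLC2A1 fell from 50.2 ± 4.16 to 35.3 ± 0.638 CPM. Of 35 nuclear-encoded genes of oxidative phosphorylation, 3 rose and 1 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.495), with ATP5G1 at 0.34 ± 0.070. Of 13 mitochondrially encoded transcripts, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.721), with MT-ND2 at 0.21 ± 0.054.

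**Figure D3:**
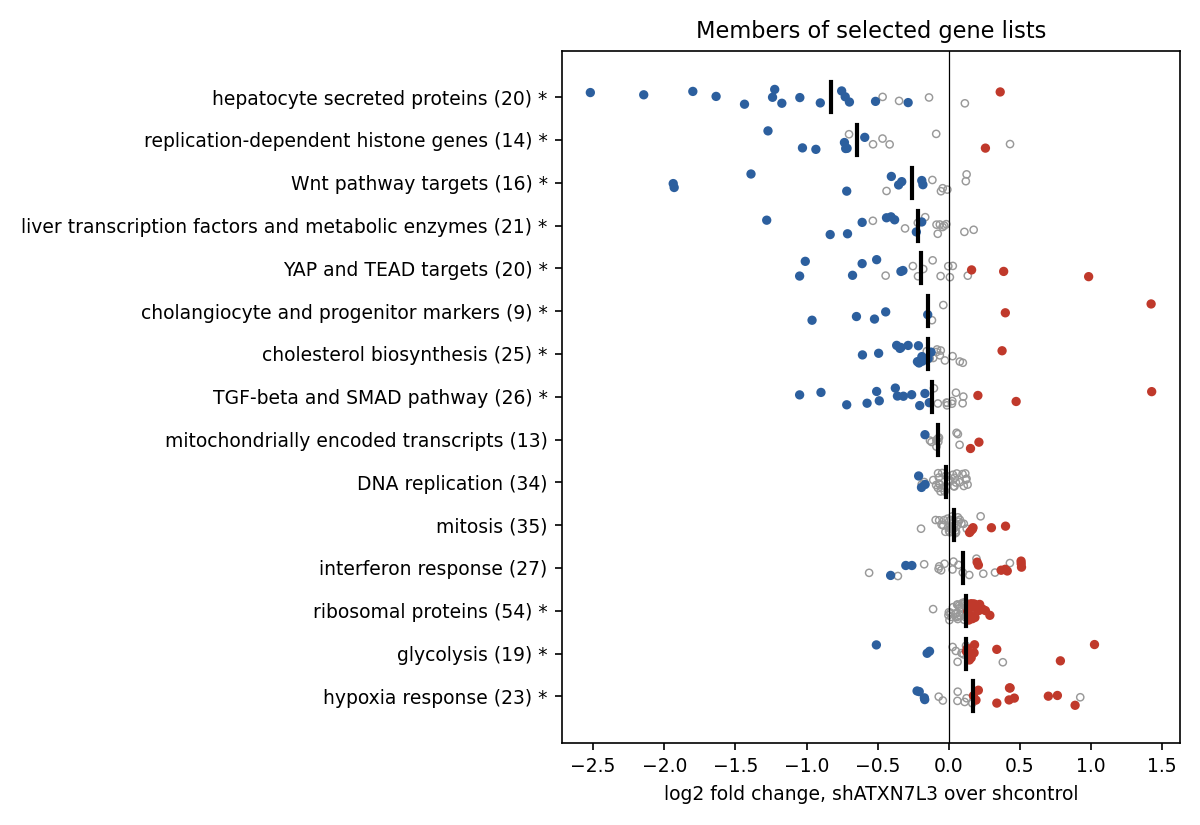
Log2 fold change of shATXN7L3 over shcontrol for the tested members of 15 lists, number tested in parentheses; filled points passed the threshold (red higher, blue lower), open points did not, bars are list medians, an asterisk marks the lists past the camera threshold, and the vertical scatter carries no value. The median of hepatocyte secreted proteins lies at -0.83 and that of ribosomal proteins at 0.12.

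Ribosomal protein genes were higher in 22 of 54 cases and lower in 0 (28 and 0 adjusted over the list alone), by small amounts (median 0.12; camera adjusted p = 7.21e-05, adjusted p = 0.687 with an estimated correlation). RPL34 went from 29.4 ± 2.57 to 35.9 ± 0.736 CPM and RPS4X from 377 ± 20.8 to 439 ± 19.4 CPM. The list's median differed by up to 0.161 on the log2 scale between single control libraries, against 0.128 between the group means. Without shcontrol replicate 3 the latter was 0.0771. Of 32 ribosome biogenesis genes, 5 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.675), with the nucleolar protein NOP58 at -0.22 ± 0.049.

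Of 27 genes of the unfolded protein and integrated stress response, 10 fell and 8 rose (10 and 9 adjusted over the list alone; median -0.02, mean 0.04, camera direction up, adjusted p = 0.68), with the stress transcription factor ATF4 (0.37 ± 0.046) and the asparagine synthetase ASNS (0.43 ± 0.058) higher and the chaperone PDIA6 (-0.33 ± 0.050) lower. Of 20 heat shock genes, 6 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.244, and 0.0167 without shcontrol replicate 3). HSPA1A (-0.44 ± 0.051) and HSPA1B (-0.46 ± 0.053) fell, but they are near-identical copies and each value is uncertain, and HSPB1 rose (0.32 ± 0.053). Of 28 immediate early genes, 6 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.904), with FOSL1 at 0.52 ± 0.055 and DUSP5 at -0.59 ± 0.052.

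Of 19 NF-kB and cytokine genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone; median -0.00, mean 0.11, camera direction up, adjusted p = 0.707). IL1B rose from 0.670 ± 0.197 to 2.95 ± 0.182 CPM and NFKB2 from 19.9 ± 0.711 to 33.4 ± 2.53 CPM, while the chemokine CXCL5 fell from 59.1 ± 3.79 to 29.2 ± 1.71 CPM and the growth factor CSF1 from 119 ± 12.6 to 60.5 ± 0.595 CPM. Of 27 interferon response genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.456), with OAS3 and OAS1 at -0.41 and -0.30 and DTX3L at 0.37. Of 29 autophagy and lysosome genes, 7 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.481), with the lysosomal protein LAMP1 at -0.50 and the cholesterol transporter NPC1 at 0.64. Of 16 estrogen response genes, 7 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.129), with IGFBP4 at -0.48.

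Of the 34 lists tested, 11 passed camera, 3 higher and 8 lower, and 1 of these 11, the hepatocyte secreted proteins, passed with an estimated correlation. Among lists that lost their call, the estimate was under the preset 0.01 for TGF-beta (-0.00781), Wnt (-0.0132), histone (-0.00132) and liver factor (0.0063) lists. A higher correlation cannot account for the loss in these. In the other lists that lost it, the estimate ran from 0.0936 (YAP and TEAD targets) to 0.832 (ribosomal proteins). By fry, which does not compare a list with other genes, 10 of the 11 moved one way on balance, and the ribosomal proteins did not pass (fry adjusted p = 0.14).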

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

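The fit without genes that overlap others on the same strand was the alternative chosen after seeing the data. ATXN7L3 stayed lower in the alternatives run, and its log2 fold change lay between -0.89 and -0.85 when 1 library was left out. DESeq2 called 1344 genes higher, beside 2182, and 1510 lower, beside 2150, and 2851 of its calls were among the 4332 of edgeR; the cause was not tested. The stricter filter, which tests fewer genes, left 92 genes at least 2-fold higher and 143 lower, beside 146 and 233, and no filter gave 186 and 328. With no filter 15 lists passed camera, newly H2B ubiquitination and PAF1 (adjusted p = 0.0311), mitosis (0.0338), p53 targets (0.0114) and estrogen response (0.0205). Tested against a fold of 1.5 with glmTreat, 153 genes were lower and 99 higher. An estimated correlation left 1 list past the threshold and fry called 19, beside 11; fry asks another question. Leaving out 1 library gave 1543 to 2224 genes higher, 1547 to 2257 lower, 132 to 165 at least 2-fold higher, 222 to 259 at least 2-fold lower, and 9 to 13 lists. The added fit gave 1857 genes higher and 1861 lower and 10 lists. Over 147 named genes and 2188 alternative values, 71 fell short of the threshold and 2 newly passed it. Among genes past the threshold in the main fit, 0 values changed direction, and such changes were not counted for the others. Replicate numbers did not pair the libraries: the correlations of same-numbered libraries were -0.124, 0.00654 and 0.0998, and shcontrol replicate 1 correlated most with shATXN7L3 replicate 2 (0.207). With the replicate number as a block, 2188 genes were higher and 2140 lower, 148 and 231 at least 2-fold, 11 lists passed and ATXN7L3 stood at -0.88. Under the block 1 named gene, RTF1, missed the threshold (edgeR adjusted p = 0.0504) and no other named gene or list changed its call. With the depth of these libraries, but a much smaller share of changed genes, the simulation recovered 71.6% of 1.5-fold changes. Scaling by library size alone put the median of all tested genes at 0.05 on the log2 scale.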

Other observations

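Gene families formed from symbol stems, a grouping chosen after the data were examined, added groups not among the fixed lists. Of 215 families with at least 8 tested members, 8 passed camera and 0 passed with an estimated correlation. Of 11 LRP genes, which encode receptors of the LDL receptor family and related proteins, 6 fell and 1 rose (camera adjusted p = 0.00154, adjusted p = 0.993 with an estimated correlation), with LRP4 at -0.62 and LRP1 at -0.58. Of 11 ADAM genes, mostly membrane-anchored metalloproteases, 5 fell and 2 rose (camera adjusted p = 0.0055, adjusted p = 0.993 with an estimated correlation). ADAM28 stood at -1.17, ADAM9 at -0.61 and ADAM23 at -2.23, and ADAM19 at 0.96. Of 30 cytochrome P450 genes, 12 fell and 2 rose (camera adjusted p = 0.00813, adjusted p = 0.993 with an estimated correlation), among them the vitamin D hydroxylase CYP24A1 at -0.71. The UGT family (12 of 13 lower) rests largely on UGT1A genes, and the PCDHA family (11 of 13 lower) on genes with common exons. Reads in those exons were counted for several genes, so such members are not separate measurements. The 1 UGT member not called lower was UGT2B7, outside the UGT1A genes, at 0.11 (edgeR adjusted p = 0.485). It does not tell how other members outside the UGT1A genes moved. The other 3 families past the threshold were HIST (14 of 26 lower), RPL (22 of 50 higher) and RPS (13 of 42 higher and 1 lower).

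The count of splits, the comparison with genes matched on GC content and length, the use of small RNA genes outside other genes and the use of the DNA replication list were chosen after seeing the data. The matched genes took the place of a smooth correction that explained 0.248% of the variance over all genes and so could hardly move a list. After that result, matched medians near 0 were likely, so the matched comparison is not independent of it. The tests of copy number and of differences between control libraries were chosen before their results were seen. The grouping gave 4332 genes past the threshold and the highest of the other splits gave 0. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. A copy number difference between the cultures was also examined. The largest absolute median among 246 blocks of 50 neighbouring genes was 0.151 ± 0.0368 (SE), under the bound of 0.2 set for it. That block lay on chromosome 5 from 159263081 to 177098144. Its absolute median exceeded 0.129, the 95th percentile of the largest block medians in 1000 shuffles of the genes (permutation p = 0.004). Genes of that block therefore moved together more than shuffled genes did. A median over 50 genes cannot show a change confined to a few neighbours. NPC1, ANKRD29 and LAMA3, which rose by 0.64, 1.95 and 1.72 on the log2 scale, lie between 23506184 and 23955066 on chromosome 18. A change confined to that stretch was not tested.

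The fall of hepatocyte plasma proteins was weighed against 2 technical explanations. The median of 393 genes outside the list, matched to its members on GC content and exonic length, was 0.0106 ± 0.0109 (SE), against -0.83 in the list, which argues against such a bias. The list's median differed by at most 0.0889 between control libraries, against -0.837 between the groups, which argues against spread of the size seen among the controls. A response to lower ATXN7L3 stays a hypothesis. Another effect of the hairpin or of the transduction is also open, since the labels do not tell how many hairpins were used or whether the libraries were separate cultures.

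The fall of histone genes could come from less carry-over of RNA without a poly-A tail. The medians of 110 tested small RNA genes without such a tail (0.0585 ± 0.0356, SE; 3 higher, 0 lower) and of the 37 without exon overlap (0.0229 ± 0.0613; 1 higher, 0 lower) go against it, but reads of the genes around them could be counted there, and the 3 outside other genes (-0.0884 ± 0.252) are too few to decide, so it stays open. The median of 215 genes matched on GC content and length was 0.031 ± 0.0223, against -0.65 in the list, which argues against that bias. A smaller share of cells in S phase predicts lower DNA replication genes, whose median was -0.019 ± 0.0241 with 3 of 34 lower and 0 higher, but how closely their mRNAs follow that share was not measured, so it also stays open. A change in histone mRNA tails was not tested.

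For the higher ribosomal protein genes, the median of 1008 genes matched on GC content and length was 0.00742 ± 0.00895 (SE), against 0.12 in the list, which argues against that bias. Differences between cultures stay a candidate explanation. The median differed by up to 0.161 between control libraries, more than the 0.128 between the groups. The former compares single libraries and the latter group means, so they are unlike quantities. All shATXN7L3 medians (0.0346 to 0.119) lay above all control medians (-0.166 to -0.00482). The lowest of the control libraries, replicate 3, lay at -0.166. Without that library the difference between the groups was 0.0771. A response to the knockdown is not excluded.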
